A study of Saccharomyces cerevisiae with 38 samples.

How the data were processed

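The 38 hybridisations were read from the deposited table, each holding a linear ratio of test over WT reference for 7056 spots; the deposited unit is a ratio, per the labels. Per the labels' protocols, polyA RNA of cells held at 37 °C for 45 minutes (OD600 of 0.8) was compared with a WT reference in the other dye. Per the series description, the authors normalized ratios by their mode in R and corrected them with Bacillus subtilis spike RNA per OD600. The labels do not say whether the deposited values come before or after those steps. Signal, background and spot quality were not analysed here.

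Groups, dyes and array letters came from the labels. For 1 array the title (hpa2 ts2) and the strain number (that of elp3) disagree, and it was kept under its title. The labels of WT arrays name no dye for the test side. Their dye sign was taken from the slide mate or the letter, which departs from the planned wording that would have used the values, with 7 from the mate and that of WT array E from the letter. Mates can differ, as slide 9 holds elp3 array B (Cy3) and hpa2 array A (Cy5). All 8 signs matched that of the correlation with the dye profile, at 0.073 for WT array B, but 3 labelled arrays did not match theirs (esa1 ts2 A at -0.039, ts2 A at -0.052 and gcn5 B at 0.017). Giving WT arrays no dye sign moved none of 19 counts by over 1.5 times. Of 342 pairs of arrays of the same dye orientation, 1 correlated below -0.3 (hpa2 array A with ts2 array A, -0.31). Its dye is stated by the labels, so its direction was kept, and the turned sign was tried as an alternative. The 2 most alike columns correlated at 0.906, and none were identical.

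Ratios were turned to log2, with values at or below 0 (0.75 to 4.23 percent per array) set to missing. By a rule fixed beforehand, array medians were subtracted if groups of 2 differed by over 0.5 in their medians more often than not, which held for 7 of 12. Spots with the same gene were averaged (30 genes). The 1477 spots without a gene name were tested apart, and 5574 of the 5579 named spots matched the gene table given. A gene was tested where at least 4 of 6 ts2 arrays, 6 of 8 WT arrays and all arrays of a group of 2 held a value, as far as the comparison used them.

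All arrays entered a single linear model per gene (limma 3.58.1 in R 4.3.3) with a coefficient for each mutant group, WT fixed at 0 as the reference of every array, and a dye term of each gene. It had 14 parameters and 24 residual degrees of freedom, and moderated tests used a prior of 2.89 degrees of freedom. WT arrays thus informed the dye term and the spread. Interactions were the double mutant less ts2 less the HAT mutant. P-values were adjusted by Benjamini and Hochberg within each comparison at 0.05. The 26 gene lists, written before any value was seen, were tested by limma's camera with a preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over all 494 tests of 19 comparisons. With the preset value 198 tests passed, and with the estimated one 0 did. On the deposited scale 182 passed, 174 of them among the 198. With limma's fry, which tests a list against no change and not against other genes, 205 passed, 148 of them among the 198. With the slide run as a block, 177 of the 198 kept their call and direction, and within a slide run 194 of 209 did.

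Named genes were chosen by a rule fixed beforehand. Only called genes with a standard name were ranked, not those known by a systematic name alone. The rule took the 10 largest rises and 10 largest falls in ts2, gcn5 and esa1, and 5 and 5 in the other comparisons with WT. These had to move the same way on every array of the group. It also took 3 and 3 in interactions, the targeted genes, and up to 3 members of each called list. Members of lists named for single strains (the a-specific genes, SLH1 across groups, and chromosome IX) were chosen after their values were seen.

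Alternatives planned beforehand were the deposited scale, no dye term, a dye term per slide run, the slide as a random block, averaged dye swaps, no filter on missing values, each slide run alone, and each array left out in turn. Another 8 were chosen after seeing the data: no dye sign for WT arrays, WT arrays left out, array weights, genes above 0 on all arrays, the slide run as a block, chromosome IX genes left out, ts2 arrays of slide run 3 left out, and the sign of hpa2 array A turned. When 1 of 2 arrays was left out, the lone array was assumed to vary like the other groups. The model was tested on simulated data. Of genes changed by 1 on the log2 scale, it recovered 91 percent in ts2, 83.6 percent in gcn5 and 55.2 percent in the esa1 interaction. Of genes changed by 0.5 it recovered 82.1, 35.8 and 9.09 percent. Over all simulated changes, 7 of 189, 10 of 155 and 3 of 107 calls were false. That noise was independent, with 1 spread per gene on all arrays, as the fit assumes. These shares therefore do not show how the fit fares where groups differ in spread or arrays share a slide. Correlations of single and double mutants with ts2 were set beside 50 simulated unchanged groups, with noise drawn independently for each gene and array. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.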

Results

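Messenger RNA of yeast (Saccharomyces cerevisiae) was compared on 38 glass arrays, each of which set a test strain against a wild-type (WT) reference in the other dye. The strains carried ts2, a mutation in 1 of 6 genes for histone acetyltransferases (HATs), or both. The ts2 mutation is a temperature-sensitive allele of TAF1, which encodes a subunit of the general transcription factor TFIID. The HAT genes were ELP3, ESA1, GCN5, HAT1, HPA2 and SAS3. Every culture was held at 37 °C for 45 minutes after growth to an optical density of about 0.8. There were 6 arrays of ts2, 8 of WT against WT, and 2 of each of the 6 HAT mutants and 6 double mutants, with the dyes exchanged between the arrays of a group. Of 7056 spots, 5579 carried 1 gene name, and these gave 5548 genes, of which 5119 had a value above 0 on all 38 arrays. Array medians of the deposited ratio ran from 0.313 to 2.5. All changes below are therefore log2 changes relative to the median gene of the array, with their standard error (SE) and the number of arrays (n). The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so p-values rest on a spread between arrays that may be technical. That spread was estimated for each gene over all groups together, so an SE is not the spread of a group's own arrays. For example, POA1 in hat1 had an SE of 0.59, with its 2 arrays at -6.01 and -0.24.

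The genes targeted in the strains were read first. GCN5, the acetyltransferase of the SAGA coactivator, fell by 2.53 on the log2 scale in gcn5 (SE 0.17, n = 2) and by 3.17 in gcn5 ts2 (SE 0.17, n = 2). On those 4 arrays it lay between -3.41 and -2.22, and on the other 34 arrays between -0.42 and 0.54. HAT1, which acetylates newly made histone H4, fell by 3.01 in hat1 (SE 0.2, n = 2) and by 3.28 in hat1 ts2 (SE 0.2, n = 2), with -0.98 to 0.98 on the other 34 arrays. SAS3, the acetyltransferase of the NuA3 complex, lay at -1.59 ± 0.4 in sas3 (n = 2), which did not pass the test (adjusted p = 0.11), and fell to -1.19 ± 0.4 in sas3 ts2 (n = 2). On those 4 arrays it lay between -2.82 and -0.37 and on 33 others between -2.15 and 0.69, so the ranges overlap and SAS3 did not settle these labels. Without either sas3 ts2 array the change was -1.21 (array A left out) or -1.17 (array B left out) and no longer passed. ELP3, the acetyltransferase subunit of Elongator, lay at 0.05 ± 0.11 on the 2 arrays labelled elp3, and between -0.86 and 0.3 on the 34 arrays without an elp3 label. The labels do not say which part of ELP3 was altered or which part its spot covers, and these arrays are called "the arrays labelled elp3" here. In elp3 ts2 ELP3 lay at -0.37 ± 0.11 (n = 2), near its -0.43 ± 0.06 in ts2 (n = 6), so those arrays too are named by label alone. HPA2 ranged from -1.07 to 1.48 on the arrays labelled hpa2 or hpa2 ts2 and from -1.75 to 2.47 on the rest, so its spot checked nothing and the arrays labelled hpa2 and hpa2 ts2 are likewise named by label alone. ESA1, the essential acetyltransferase of NuA4, rose by 0.97 ± 0.29 in esa1 (n = 2) and by 0.77 ± 0.29 in esa1 ts2 (n = 2). Neither call held when an array of its group was left out (0.99 and 0.95 in esa1, 0.79 and 0.76 in esa1 ts2, without array A and B). In esa1 ts2 the value turned to -0.26 on the deposited scale. TAF1 rose by 0.27 ± 0.08 in ts2 (n = 6), and that value turned to -0.09 without the median subtraction.

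**Figure D1:**
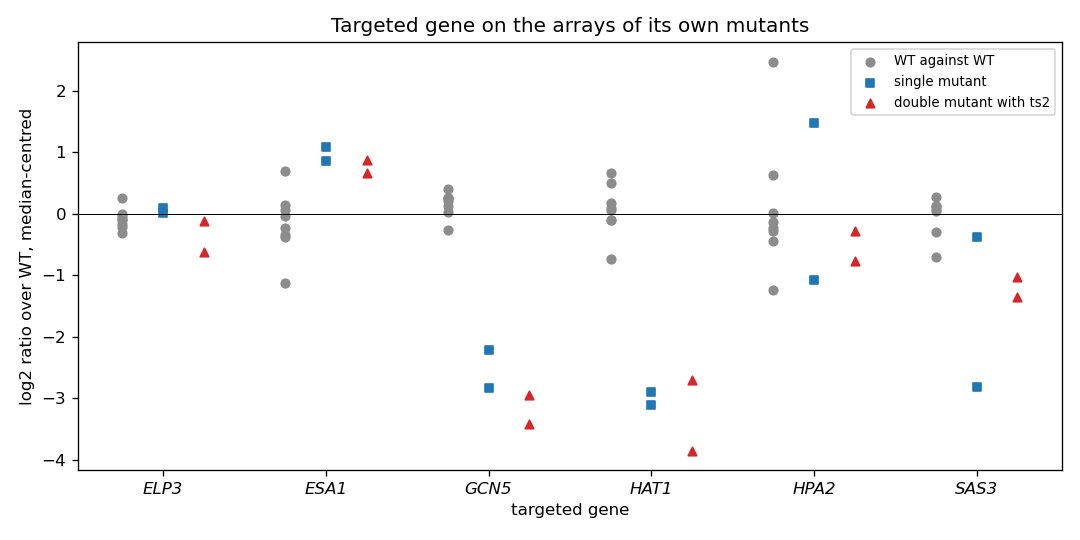
Log2 ratio to the WT reference (vertical axis, median of the array subtracted) of the targeted genes on each array, 1 point per array. GCN5 lay between -3.41 and -2.22 on its 4 arrays and HAT1 between -3.85 and -2.7 on its 4 arrays, below all other arrays.

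The ts2 allele alone was compared with WT to ask which genes change when TAF1 is impaired at 37 °C. Many stress and carbon metabolism genes rose and many genes for making ribosomes fell, though no list call passed with an estimated correlation. Among genes with a standard name, the largest rise was that of SLH1, a putative RNA helicase (3.79 ± 0.12, n = 6). On the ts2 arrays of slide run 3 SLH1 lay at 4.51 and 4.55, and on those of the other runs at 3.3 to 3.62. Next were the small heat shock protein gene HSP26 (3.06 ± 0.14) and TFS1 (3.0 ± 0.15), which encodes a carboxypeptidase Y inhibitor. The stress gene DDR2 followed (2.99 ± 0.14). Of the same genes, the largest fall was that of MF(ALPHA)2, which encodes the alpha-factor pheromone (-3.46 ± 0.16, n = 6). It came ahead of RNH203 (-2.5 ± 0.13), a subunit of ribonuclease H2, and BIO2 (-2.41 ± 0.11), the biotin synthase gene. Further rises above 2.7 were those of FMP45 (2.98), the aconitase gene ACO1 (2.96), the catalase gene CTT1 (2.8), the arginine synthesis genes ARG1 (2.78) and ARG3 (2.77), and MMS22 (2.76), which acts in DNA repair. Further falls were those of BNA1 (-2.14), which acts in NAD synthesis, the thioredoxin gene TRX1 (-1.95), RPL9A (-1.95), ASC1 (-1.86), RPS28A (-1.85), SAM4 (-1.84) and REA1 (-1.84). The call of each of these 20 genes held whichever of the 14 ts2 and WT arrays was left out. RPL9A and RPS28A each have a near-identical copy that the spot could also capture.

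Of 134 ribosomal protein genes, 127 fell and 1 rose in ts2, with a median of -1.01, against -0.18 to 0.28 on the 8 WT arrays. RPP1A (-1.54 ± 0.07), RPL26A (-1.43 ± 0.07) and RPL2B (-1.42 ± 0.07) were among them, and adjusted over the list alone 128 fell. The set test gave an adjusted p of 1.8e-34, and adjusted p = 0.16 with an estimated correlation. Ribosome biogenesis genes went the same way, with 78 of 105 lower and 3 higher (median -0.48, adjusted p = 9.7e-08, and adjusted p = 0.28 with an estimated correlation), including SDA1 (-1.19 ± 0.08) and UTP20 (-1.17 ± 0.07). MAK5, a helicase of this list, rose (1.37 ± 0.07). Of 63 targets of the stress activators Msn2 and Msn4, 58 rose and 1 fell, with the same counts adjusted over the list alone. Their median was 1.59, against -0.24 to 0.13 on the WT arrays (adjusted p = 7.9e-31, and adjusted p = 0.095 with an estimated correlation). The glucokinase gene GLK1 (2.68 ± 0.07), the peroxiredoxin gene PRX1 (2.43 ± 0.07) and the protease gene PRB1 (2.11 ± 0.08) were examples. Of 16 glycolysis genes 15 rose and 1 fell, and the list alone gave the same counts (median 1.62, adjusted p = 1.5e-24, and adjusted p = 0.15 with an estimated correlation). TDH1 rose by 2.02 ± 0.08 and ADH1 by 1.79 ± 0.07. Within slide runs 2, 3 and 4 the ribosomal protein median was -1.12, -0.96 and -0.9 (-1.02 with the slide run as a block). The Msn2/4 median was 1.74, 1.6 and 1.44 (1.62 as a block) and that of glycolysis 1.57, 1.75 and 1.65 (1.69 as a block).

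Cell wall integrity genes rose in 23 of 26 cases with none lower (median 1.11, adjusted p = 6.3e-10, and adjusted p = 0.16 with an estimated correlation), among them CCW12 (1.14 ± 0.07), a structural mannoprotein gene. Of 69 amino acid synthesis genes under the activator Gcn4, 43 rose and 12 fell, with 44 and 12 adjusted over the list alone (median 0.52, adjusted p = 2.1e-09, and adjusted p = 0.3 with an estimated correlation). GCV1 rose by 2.03 ± 0.07 and ARG4 by 1.84 ± 0.07. Of the 4 alpha-specific genes all fell, among them the pheromone receptor gene STE3 (-1.14 ± 0.1) and MF(ALPHA)1 (-1.46 ± 0.13). Their median was -1.6 (adjusted p = 0.00051, and adjusted p = 0.25 with an estimated correlation), and 1 WT array lay at -0.75. Of the COS and PAU families near chromosome ends, 24 of 41 fell and 1 rose, for example PAU6 (-1.0 ± 0.09), with a median of -0.48 (adjusted p = 0.0048, and adjusted p = 0.45 with an estimated correlation). On ts2 array B their median was -0.95 and on the other ts2 arrays -0.41 to -0.13, and within slide runs 2 and 4, without that array, it was -0.37 and -0.33. Members of each family are alike in sequence and cannot be parted by their spots. The genes used as strain markers rose in 6 of 8 cases and fell in 1 (median 0.81, adjusted p = 0.00052, and adjusted p = 0.24 with an estimated correlation), for example ADE2 (1.8 ± 0.06). Heat shock factor (Hsf1) chaperone genes rose in 19 of 32 cases and fell in 4 (median 0.45, adjusted p = 0.00076, and adjusted p = 0.37 with an estimated correlation). The TCA and glucose-repressed genes had 20 of 38 higher and 5 lower, with IDH1 at 2.16 ± 0.07 (adjusted p = 2.6e-07, and adjusted p = 0.24 with an estimated correlation). Their median of 0.35 turned to -0.01 on the deposited scale. The medians of the proteasome list (0.23, with 21 of 36 higher and 4 lower) and of the G2/M and M/G1 list (0.11, with 16 of 37 higher and 9 lower) turned to -0.14 and -0.26 there. Their adjusted p-values were 0.034 and 0.026, and adjusted p = 0.58 and 0.62 with an estimated correlation. WT array A lay at 0.3 for the proteasome and WT array H at 0.16 for G2/M and M/G1, each above the ts2 median, with the other WT arrays at -0.1 to 0.06 and -0.07 to 0.02. The G2/M and M/G1 list was no longer called with the slide run as a block (adjusted p = 0.054). Within slide runs 2 and 4 neither list was (G2/M and M/G1: adjusted p = 0.13 and 0.054, proteasome: 0.25 and 0.056).

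Lists whose set test missed in ts2 still held changed members. The pheromone response list had 13 of 26 higher and 1 lower (adjusted p = 0.06). The iron regulon had 17 of 29 higher and 8 lower (adjusted p = 0.15). The phosphate (PHO) regulon had 11 of 21 higher and 4 lower (adjusted p = 0.13). Its median was 0.93 and 1.01 on ts2 arrays D and F, and -0.01 to 0.19 on the other ts2 arrays. Of 38 oxidative phosphorylation genes 20 rose and 9 fell (adjusted p = 0.099), of 47 G1/S genes 21 rose and 13 fell (adjusted p = 0.6), and of 6 Elongator genes 4 fell (adjusted p = 0.087). Among genes for TFIID subunits 6 of 15 rose and 2 fell, for SAGA subunits 4 of 19 rose and 6 fell, and for NuA4 subunits 4 of 13 rose and 2 fell. Histone genes had 5 of 11 higher and 2 lower, phospholipid synthesis genes 5 of 17 higher and 7 lower, and none of 7 a-specific genes passed. In all, 3617 of 5546 genes passed the limma test, 1776 higher and 1841 lower, and 367 of the higher and 266 of the lower changed at least 2-fold. On the deposited scale the median gene of ts2 lay at -0.35 and 2138 passed, 384 higher and 1754 lower. Within slide runs 2, 3 and 4 alone, 3389, 3439 and 2600 genes passed.

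**Figure D2:**
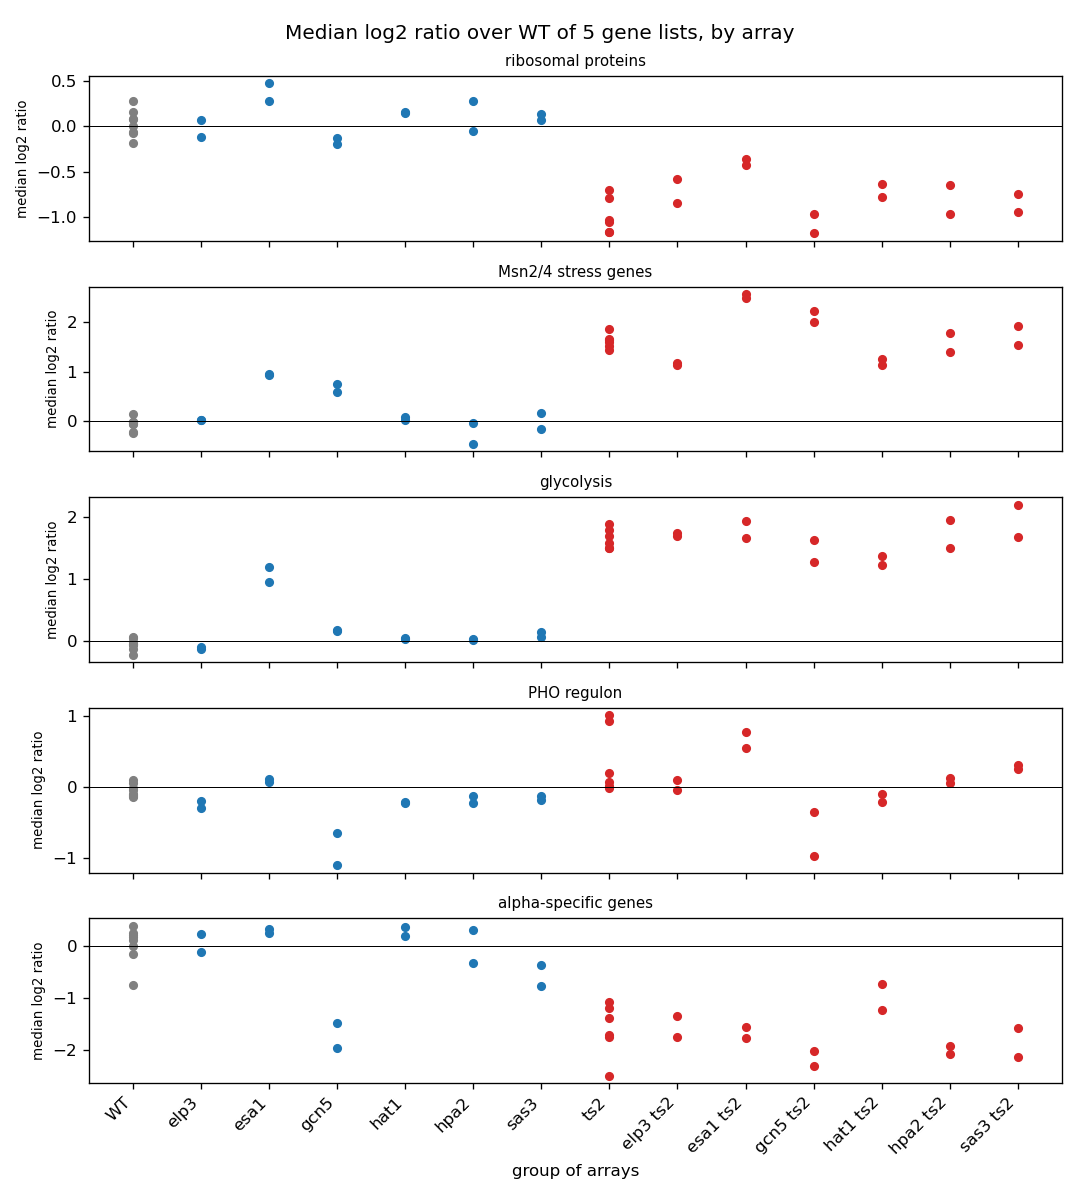
Median log2 ratio to WT (vertical axes) of 5 gene lists on each array, by group of arrays (horizontal axis), 1 point per array. Ribosomal proteins lay at -0.18 to 0.28 on the WT arrays, and their median change in ts2 was -1.01.

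The gcn5 mutant was compared with WT to ask which genes change without this HAT. Many phosphate and mating genes fell and many stress genes rose, but none of the list calls below passed with an estimated correlation. MF(ALPHA)2 fell to -3.23 ± 0.28 (n = 2), the phosphate transporter gene PHO84 to -3.2 ± 0.52, SPL2 to -2.26 ± 0.37, the alpha-agglutinin gene SAG1 to -2.05 ± 0.29 and the polyphosphate synthesis gene VTC3 to -1.75 ± 0.28. DDR2 rose by 2.63 ± 0.25 (n = 2), CAK1, which encodes a kinase that activates Cdc28, by 2.45 ± 0.5, the Hsp70 gene SSA3 by 2.36 ± 0.57, SPG4 by 2.28 ± 0.37 and HSP26 by 2.02 ± 0.24. Further rises were those of the carbonic anhydrase gene NCE103 (2.04), VID24 (1.88), CTT1 (1.88), the methionine permease gene MUP1 (1.86) and PDH1 (1.85). Further falls were those of NDJ1 (-1.81), SPR6 (-1.66), the glycogen synthase gene GSY1 (-1.65) and the flavohemoglobin gene YHB1 (-1.62). Of these 20 named genes, GCN5 included, 17 kept their call whichever array was left out. SSA3 lost it without gcn5 array A (1.88), NCE103 without gcn5 array B (1.62) and PDH1 without either (1.91 and 1.79).

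Of 21 PHO regulon genes 13 fell in gcn5 and 1 rose, with the same counts adjusted over the list alone (median -0.84, adjusted p = 5.2e-07, and adjusted p = 0.19 with an estimated correlation). All 4 alpha-specific genes fell (median -1.73, adjusted p = 6.9e-09, and adjusted p = 0.11 with an estimated correlation). Of 26 pheromone response genes 11 fell and none rose, and 13 fell adjusted over the list alone (median -0.51, adjusted p = 3.8e-05, and adjusted p = 0.066 with an estimated correlation). The mating kinase gene FUS3 fell by 0.82 (SE 0.12) and SST2, a regulator of the pheromone signal, by 1.17 (SE 0.17). Msn2/4 genes rose in 33 of 63 cases and fell in 3, with 34 and 4 adjusted over the list alone (median 0.61, adjusted p = 6.3e-12, and adjusted p = 0.22 with an estimated correlation). Oxidative phosphorylation genes rose in 10 of 38 cases and fell in 1 (median 0.34, adjusted p = 2.6e-05, and adjusted p = 0.19 with an estimated correlation), for example ATP15 (1.15 ± 0.18). Ribosome biogenesis genes rose in 16 of 105 cases (median 0.21, adjusted p = 0.00057, and adjusted p = 0.51 with an estimated correlation). The ribosomal protein list had 19 of 134 lower and 1 higher, and its median of -0.14 turned to 0.05 on the deposited scale (adjusted p = 0.0012, and adjusted p = 0.69 with an estimated correlation). That list was no longer called with the slide run as a block (adjusted p = 0.058). In all, 1025 of 5542 genes passed, 507 higher and 518 lower. The count was 419 without gcn5 array A, 504 without array B, 474 with the slide run as a block and 1779 within the slide run of gcn5, and on the deposited scale, where the median gene lay at 0.19, 29 passed, 23 higher and 6 lower.

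The esa1 mutant was compared with WT in the same way. Glycolysis, stress and amino acid genes mostly rose, with no list call that passed with an estimated correlation. DDR2 rose by 1.88 ± 0.25 (n = 2), YCH1, a phosphatase gene, by 1.87 ± 0.17, ARG3 by 1.86 ± 0.32, FMP45 by 1.86 ± 0.33, PBI2 by 1.85 ± 0.19, HSP26 by 1.84 ± 0.24, CTT1 by 1.78 ± 0.26 and the ribonucleotide reductase gene RNR4 by 1.77 ± 0.14. IMA2 fell by 1.52 (SE 0.27), EFM3 by 1.33 (SE 0.16) and GON7 by 1.3 (SE 0.23). IMA3, an isomaltase gene close in sequence to IMA2, lies on chromosome IX, as does EST3, a telomerase gene. They lay at -1.39 ± 0.15 and -1.6 ± 0.37, and the 205 genes of that chromosome had a median of -0.41 in esa1, with 90 lower and 9 higher. Other genes lost their call without 1 array. Those that moved by over 1.5 times were ARP7 (-1.7, and -0.98 without esa1 array A), and without esa1 array B BNA2 (3.64, and 1.51), the condensin gene BRN1 (-3.01, and -1.98), NOP4 (-1.97, and -0.37) and ADH7 (-1.45, and -0.79). Those that moved less were EST3 (-1.59) and the vitamin synthesis gene SNZ3 (-1.26, and -0.99) without array A, and the glutathione reductase gene GLR1 (2.39, and 2.56 and 2.22 without array A and B).

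All 16 glycolysis genes rose in esa1 (median 1.07, adjusted p = 1.3e-24, and adjusted p = 0.066 with an estimated correlation), among them PGI1 (1.08 ± 0.09) and PFK2 (1.04 ± 0.1). Of 63 Msn2/4 genes 44 rose and 1 fell, with 47 and 1 adjusted over the list alone (median 0.95, adjusted p = 2.1e-17, and adjusted p = 0.15 with an estimated correlation). Gcn4 genes rose in 40 of 69 cases and fell in 2 (median 0.51, adjusted p = 1.5e-12, and adjusted p = 0.17 with an estimated correlation), for example ARG4 (1.6 ± 0.13). Cell wall integrity genes rose in 20 of 26 cases, 23 adjusted over the list alone (median 0.72, adjusted p = 1.1e-10, and adjusted p = 0.15 with an estimated correlation). Of 11 histone genes 8 rose, among them HHT2 (1.0 ± 0.12), which encodes histone H3 and has a near-identical copy in HHT1 (median 0.68, adjusted p = 0.00064, and adjusted p = 0.31 with an estimated correlation). G1/S genes rose in 21 of 46 cases and fell in 1, including the cyclin genes PCL2 (0.8 ± 0.09) and CLN2 (1.03 ± 0.18). That list had a median of 0.52 (adjusted p = 9.2e-05, and adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes rose in 65 of 134 cases with none lower, and 74 rose adjusted over the list alone, but their median of 0.39 turned to -0.05 on the deposited scale (adjusted p = 1.1e-09, and adjusted p = 0.37 with an estimated correlation). Ribosome biogenesis genes fell in 20 of 105 cases and rose in 2 (median -0.13, adjusted p = 0.0011, and adjusted p = 0.56 with an estimated correlation). In all, 1591 of 5520 genes passed, 936 higher and 655 lower. The count was 602 without esa1 array A, 774 without array B, 861 with the slide run as a block and 2338 within the slide run of esa1, and on the deposited scale, where the median gene lay at -0.44, 4 passed, 1 higher and 3 lower.

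The arrays labelled elp3, hat1, hpa2 and sas3 were compared with WT in the same way. Few genes passed. In sas3 FDC1, a decarboxylase gene, fell by 1.46 (SE 0.11, n = 2). In hat1 the vacuolar calcium pump gene PMC1 fell by 1.96 (SE 0.2, n = 2) beside HAT1 itself. On the arrays labelled elp3 the sporulation kinase gene SPS1 fell by 2.67 (SE 0.29, n = 2), and the cell wall iron genes FIT2 (1.16 ± 0.2) and FIT3 (0.89 ± 0.2) rose. Of these, FIT2 lost its call without elp3 array B (1.16), and FIT3 without either elp3 array (0.93 and 0.86). Some genes lost their call with 1 array fewer while their change hardly moved. On the arrays labelled elp3 these were the ribosome assembly gene BMS1 (-3.43 ± 0.53, and -3.32 without array B) and TTI1 (-1.95 ± 0.44, and -1.9 and -2.01 without array A and B). In sas3 it was GSY1 (-0.92 ± 0.19, and -0.99 and -0.85 without array A and B), whose call also lapsed at -0.92 without WT array B, C or F. Other named genes moved by over 1.5 times without 1 array. On the arrays labelled elp3 they were JSN1 (-1.62, and -0.24 without array A), the clathrin gene CHC1 (-1.49, and -0.5 without array B), MRX6 (2.19, and 0.78), DLD3 (0.8, and 0.37) and UTR2 (0.73, and 0.32). For hat1 they were POA1 (-3.13 ± 0.59, and -0.08 without array B), RNY1 (-2.81, and -0.23), LAM1 (-2.75, and 0.01), EMC6 (1.81, and 0.12), PSY3 (0.86, and 0.16) and STE4 (0.83, and 0.23). For sas3 they were VPS3 (-2.72 ± 0.51, and -1.48 without array A), RGD3 (-2.18, and -0.25) and MSB3 (-1.83, and -0.11). On the arrays labelled hpa2 they were all 10 named genes, among them VPS17 (-2.19 ± 0.41, and -0.49 without array B), ATP20 (-1.98, and -0.35), NOT5 (1.84, and 0.5) and SNT309 (1.73, and 0.42).

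Across all genes, the 2 arrays labelled elp3 correlated at 0.08, those of hat1 at -0.15, those labelled hpa2 at -0.03 and those of sas3 at 0.1, against 0.66 in gcn5 and 0.68 in esa1. Genes are not independent replicates. Array A of hpa2 correlated at -0.31 with array A of ts2, of the same dye orientation. With its sign turned, 7 genes passed in hpa2 in place of 22. Set tests called lists in which few or no genes passed. In sas3 14 lists were called. The largest shift among them was that of the 4 alpha-specific genes (median -0.65, with 0 passing and 2 lower adjusted over the list alone, adjusted p = 0.0003, and adjusted p = 0.17 with an estimated correlation). The sas3 arrays lay at -0.38 and -0.78 there, and 1 WT array at -0.75. Proteasome genes tested higher in sas3 (median 0.12, with 0 of 36 genes passing, adjusted p = 7.6e-07, and adjusted p = 0.25 with an estimated correlation). Ribosomal protein genes did so in hat1 (median 0.16, with 0 of 133 passing, adjusted p = 1.2e-13, and adjusted p = 0.3 with an estimated correlation), and proteasome genes on the arrays labelled elp3 (median 0.16, with 0 of 36 passing, adjusted p = 6.3e-06, and adjusted p = 0.3 with an estimated correlation). The hat1 arrays (0.15 and 0.16) lay within the -0.18 to 0.28 of the WT arrays for ribosomal proteins, and WT array A lay at 0.3 for the proteasome. Msn2/4 genes tested lower on the arrays labelled hpa2 (median -0.25, with 0 of 62 passing and 8 lower adjusted over the list alone, adjusted p = 1.6e-07, and adjusted p = 0.28 with an estimated correlation). Array A, whose sign is in doubt, lay at -0.47, and array B at -0.05, within the -0.24 to 0.13 of the WT arrays. On the arrays labelled elp3 the proteasome median was 0.04 with the slide run as a block (adjusted p = 0.69). Counts that passed were 25 of 5533 on the arrays labelled elp3 (9 higher, 16 lower), 31 of 5423 in hat1 (4 higher, 27 lower), 22 of 5491 on those labelled hpa2 (13 higher, 9 lower) and 9 of 5505 in sas3 (0 higher, 9 lower). On the deposited scale they were 2 higher and 1 lower in elp3, 3 and 4 in hat1, 2 and 0 in hpa2, and 0 and 2 in sas3, with the median gene at 0.76, 0.48, -0.12 and 0.19. Without array A or B of the mutant, the counts were 62 and 16 in elp3, 66 and 58 in hat1, 40 and 231 in hpa2 and 21 and 20 in sas3, and without WT array A the count in elp3 was 53. With the slide run as a block they were 5, 2, 1 and 2 in elp3, hat1, hpa2 and sas3, and within the mutant's own slide run 0 in elp3, where 493 genes had an unadjusted p under 0.05 in limma, 2 in hat1 and 1 in sas3.

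The effects of ts2 and of each HAT mutant were set against each other over all genes, as the series title relates TAF1 to the HATs. The ts2 and esa1 changes correlated at 0.5 over 5520 genes, and the ts2 and gcn5 changes at 0.32 over 5542 genes. Of genes called in both, 599 were higher in ts2 and in esa1, where independent lists would share 301, and 433 were lower in both, where they would share 218. Another 75 were higher in ts2 and lower in esa1 and 182 the reverse, where independent lists would share 211 and 312. For gcn5 these counts were 339 higher in both (162 from independent lists), 296 lower in both (172), 127 higher in ts2 and lower in gcn5 (166) and 92 the reverse (168). All arrays share the WT reference. Simulated unchanged groups gave correlations of at most 0.086 beside esa1 and 0.064 beside gcn5. They held independent noise on each array, so they do not show what a shared reference or genes that vary together would add. Pairs of WT arrays correlated at -0.18 to 0.21. The covariance was 0.15 for esa1 and 0.086 for gcn5, beside simulated covariances of -0.00018 and 2e-04. With ts2 arrays from other slide runs only, the correlations were 0.46 and 0.29. The correlation with ts2 was -0.03 for elp3, -0.02 for hat1 and -0.01 for sas3, and -0.21 for hpa2 (-0.28 for array A and 0 for array B).

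**Figure D3:**
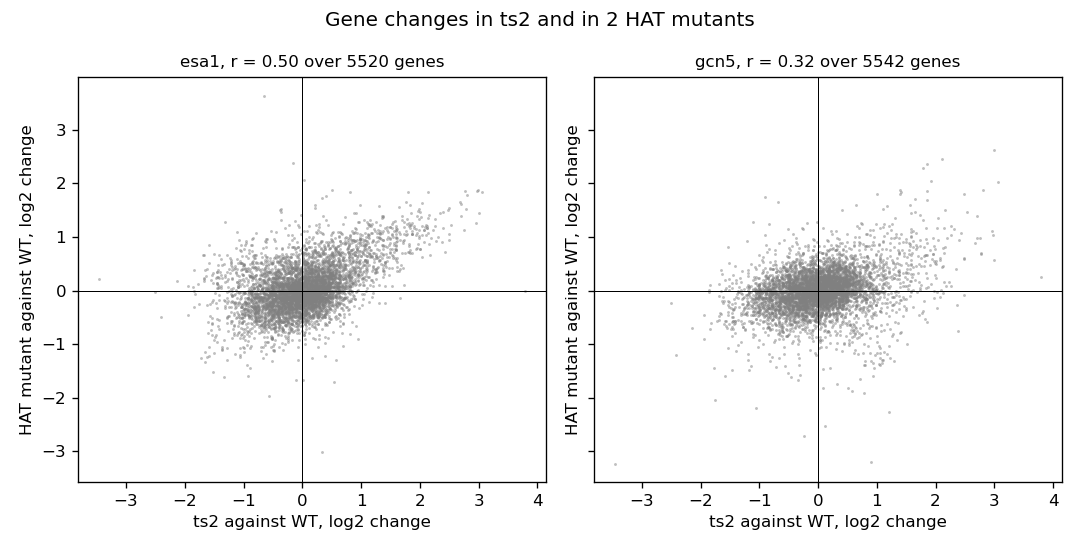
Log2 change of each gene in ts2 (horizontal axes) against its log2 change in esa1 (left) and gcn5 (right), 1 point per gene. The correlation was 0.5 over 5520 genes for esa1 and 0.32 over 5542 genes for gcn5.

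Arrays labelled as double mutants were compared with WT to ask what ts2 does in each HAT background. In all 6, DDR2 and SLH1 rose and MF(ALPHA)2 fell, ribosomal protein genes tested lower and Msn2/4 and glycolysis genes tested higher. None of these list calls passed with an estimated correlation. The changes correlated with those of ts2 at 0.92 in sas3 ts2, 0.85 in esa1 ts2, 0.83 in hat1 ts2 and in hpa2 ts2, 0.78 in elp3 ts2 and 0.76 in gcn5 ts2. Both sides share the WT reference, and genes are not independent replicates. Simulated unchanged groups gave at most 0.053, 0.085, 0.056, 0.044, 0.07 and 0.044 in that order. Their noise was independent on each array, so a shared reference and genes that vary together were not simulated. Genes called with the same sign in both numbered 2527, 2535, 1616, 2153, 1879 and 2308, where independent lists would share 872, 1018, 567, 817, 716 and 979. In gcn5 ts2 DDR2 rose by 5.33 ± 0.25 (n = 2), CTT1 by 4.97 ± 0.26, SSA3 by 4.65 ± 0.57, HSP26 by 4.55 ± 0.24 and AGA2, which encodes the adhesion subunit of a-agglutinin, by 4.53 ± 0.47. MF(ALPHA)2 (-3.89 ± 0.28), PHO84 (-3.6 ± 0.52), AFB1 (-3.38 ± 0.16), which encodes a blocker of a-factor, and BIO2 (-3.0 ± 0.18) fell with GCN5. Of 7 a-specific genes 3 rose in gcn5 ts2, the others being the a-factor gene MFA2 (4.07 ± 0.31) and the alpha-factor receptor gene STE2 (2.96 ± 0.32). MFA1 lay at 2.1 ± 0.94, which did not pass (adjusted p = 0.061). The list had a median of 2.1 (adjusted p = 0.025, and adjusted p = 0.27 with an estimated correlation). All 4 alpha-specific genes fell in the same strain (median -2.12, adjusted p = 0.00019, and adjusted p = 0.22 with an estimated correlation). Pheromone response genes rose in 12 of 26 cases and fell in 3, but their median of 0.29 turned to -0.3 on the deposited scale (adjusted p = 0.038, and adjusted p = 0.31 with an estimated correlation). Within the slide run of gcn5 ts2 that list was not called (adjusted p = 0.057). Msn2/4 genes rose in 51 of 63 cases and fell in 2 (median 2.09, adjusted p = 2.1e-30, and adjusted p = 0.11 with an estimated correlation), and ribosomal protein genes fell in 121 of 134 cases and rose in 1 (median -1.07, adjusted p = 2.3e-25, and adjusted p = 0.19 with an estimated correlation). Glycolysis genes rose in 15 of 16 cases and fell in 1 (median 1.4, adjusted p = 2.2e-11, and adjusted p = 0.17 with an estimated correlation). In all, 2998 of 5540 genes passed, 1465 higher and 1533 lower, and 211 higher and 1204 lower on the deposited scale, where the median gene lay at -0.59.

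In esa1 ts2 SLH1 rose by 4.98 ± 0.2 (n = 2). Both esa1 ts2 arrays were of slide run 3, where SLH1 lay at 4.51 and 4.55 on the ts2 arrays. The methionine synthesis gene STR3 rose by 4.61 ± 0.4 and CTT1 by 4.61 ± 0.26. DDR2 rose by 4.34 ± 0.25 and the aldehyde dehydrogenase gene ALD3 by 4.27 ± 0.33. SNZ3 fell by 3.49 (SE 0.31), the hexose transporter gene HXT16 by 3.44 (SE 0.43), the sorbitol dehydrogenase gene SOR2 by 3.36 (SE 0.22) and RNH203 by 3.06 (SE 0.23). FMT1 fell by 2.86 (SE 0.86) and lost its call without esa1 ts2 array B (-0.52). SNZ3, HXT16 and SOR2 have near-identical copies. Msn2/4 genes rose in 59 of 63 cases (median 2.47, adjusted p = 6.4e-35, and adjusted p = 0.08 with an estimated correlation) and oxidative phosphorylation genes in 28 of 38, 29 adjusted over the list alone (median 1.04, adjusted p = 1.6e-06, and adjusted p = 0.15 with an estimated correlation). The succinate dehydrogenase gene SDH2 (2.26 ± 0.15) and the cytochrome c1 gene CYT1 (2.17 ± 0.15) were among the latter. Glycolysis genes rose in 15 of 16 cases and fell in 1 (median 1.76, adjusted p = 2e-15, and adjusted p = 0.15 with an estimated correlation). Ribosomal protein genes fell in 76 of 134 cases and rose in 7, RPS14B among them (1.92 ± 0.15), with a median of -0.39 (adjusted p = 0.0005, and adjusted p = 0.63 with an estimated correlation). Gcn4 genes rose in 50 of 69 cases and fell in 6, but their median of 0.84 turned to -0.19 on the deposited scale (adjusted p = 3.9e-13, and adjusted p = 0.19 with an estimated correlation). COS and PAU genes fell in 29 of 41 cases and rose in 2 (median -0.76, adjusted p = 5.6e-06, and adjusted p = 0.28 with an estimated correlation). On chromosome IX 81 of 206 genes fell and 39 rose (median -0.19). In all, 3114 of 5530 genes passed, 1536 higher and 1578 lower. The deposited scale gave 209 higher and 2836 lower, with the median gene at -1.02.

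The other 4 double mutants were described by the same genes. SLH1 rose by 3.12 ± 0.2 in elp3 ts2, 3.39 ± 0.2 in hat1 ts2, 3.01 ± 0.2 in hpa2 ts2 and 3.68 ± 0.2 in sas3 ts2 (n = 2 each). DDR2 rose by 2.9 ± 0.25, 2.43 ± 0.25, 3.58 ± 0.25 and 3.53 ± 0.25, and FMP45 by 2.96 ± 0.33, 2.26 ± 0.33, 3.42 ± 0.33 and 3.15 ± 0.33 in the same order. MF(ALPHA)2 fell to -2.91, -2.89, -2.96 and -3.87 (SE 0.28 each). In sas3 ts2 FDC1 fell by 3.02 (SE 0.11). In hat1 ts2 the permease gene AGP3 fell by 2.98 (SE 0.4) and GLK1 rose by 2.23 (SE 0.13). In elp3 ts2 ARG3 rose by 3.11 (SE 0.32) and INA1 fell by 2.1 (SE 0.15). In hpa2 ts2 RNH203 fell by 2.49 (SE 0.23) and REA1 by 2.39 (SE 0.16). Some named genes lost their call without 1 array of the group. They were CRZ1 (-2.34, and -0.42 without elp3 ts2 array A), ULA1 (-2.26, and -1.16 without it), PRP4 (-3.23, and -0.42 without hat1 ts2 array A), NUP85 (2.99, and 1.76 without hat1 ts2 array B), SET5 (-3.17, and -0.38 without it), PDR3 (2.92, and 0.61 without hpa2 ts2 array B), HXT16 (-2.55, and -0.42 without it) and IMA4 (-2.65, and -1.26 without sas3 ts2 array A). The labels of hpa2 ts2 array A disagree, since its title names hpa2 ts2 and its strain number is that of elp3. It was kept under its title. SLH1 lay at 2.91 on it, as on ts2 arrays, against -0.05 and 0.29 on the arrays labelled elp3, which does not tell hpa2 ts2 from elp3 ts2 (3.08 and 3.16).

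Msn2/4 genes rose in 49 of 63 cases in elp3 ts2, 48 of 62 in hat1 ts2, and 54 of 63 in hpa2 ts2 and in sas3 ts2, with none lower in any. Their medians were 1.18, 1.15, 1.55 and 1.69 (adjusted p = 1e-20, 2.3e-30, 4.1e-28 and 4.9e-30, and adjusted p = 0.15, 0.08, 0.087 and 0.086 with an estimated correlation). Ribosomal protein genes fell in 104, 116, 110 and 115 of 134 cases and rose in 2, 2, 2 and 1. Their medians were -0.69, -0.69, -0.79 and -0.84 (adjusted p = 2.5e-21, 1.9e-31, 1.7e-20 and 1.1e-20, and adjusted p = 0.22, 0.15, 0.23 and 0.22 with an estimated correlation). Adjusted over the list alone, 112, 121, 116 and 116 fell. Glycolysis genes rose in 15 of 16 cases in each, with medians of 1.72, 1.28, 1.73 and 1.95 (adjusted p = 1.5e-31, 8.4e-27, 2.5e-24 and 8.4e-28, and adjusted p = 0.066, 0.066, 0.091 and 0.086 with an estimated correlation). The iron regulon tested higher in elp3 ts2 (median 0.19, 11 of 29 higher and 4 lower, adjusted p = 0.022, and adjusted p = 0.15 with an estimated correlation) and in hpa2 ts2 (median 0.36, 10 of 29 higher and 3 lower, adjusted p = 0.025, and adjusted p = 0.15 with an estimated correlation). The iron-sulfur scaffold gene ISU1 rose by 2.2 ± 0.16 in both. With the slide run as a block the iron call in hpa2 ts2 was lost (adjusted p = 0.058). The genes that passed were 1093 higher and 1099 lower in elp3 ts2, 823 and 902 in hat1 ts2, 1205 and 1294 in hpa2 ts2, and 1316 and 1349 in sas3 ts2. On the deposited scale they were 142 higher and 36 lower, 111 and 7, 205 and 129, and 211 and 259, with the median gene at 0.01, 0.28, -0.07 and -0.2. Without array A or B of hat1 ts2, 1069 and 697 genes passed there, and without array A of sas3 ts2, 1719 passed there.

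Interaction terms asked whether the effect of ts2 differed between a HAT mutant and the WT background, as the change in the double mutant less those of ts2 and of the HAT mutant. Among genes with a standard name, the interaction in gcn5 was largest for the a-specific genes AGA2 (3.76 ± 0.72) and MFA2 (3.52 ± 0.48). For MF(ALPHA)2, which fell by 3.46 in ts2, by 3.23 in gcn5 and by 3.89 in gcn5 ts2, it was 2.8 ± 0.43. Signal over background was not analysed, so a floor of its spot below which no further fall could be read was not excluded. Pheromone response genes tested higher, with 9 of 26 higher, but their median of 0.32 turned to -0.1 on the deposited scale (adjusted p = 1.1e-10, and adjusted p = 0.066 with an estimated correlation). The a-specific list had 3 of 7 higher (median 1.1, adjusted p = 1.8e-06, and adjusted p = 0.066 with an estimated correlation). Lower were ARG1 (-1.38 ± 0.31), FIT2 (-1.27 ± 0.31) and HOM3 (-1.17 ± 0.25), and Gcn4 genes had 4 of 69 lower and none higher, with 10 lower and 2 higher adjusted over the list alone (median -0.21, adjusted p = 6.4e-07, and adjusted p = 0.3 with an estimated correlation). MFA2 and MF(ALPHA)2 kept their calls whichever array was left out. Without gcn5 ts2 array A or gcn5 array B AGA2 lost its call (2.97 and 3.31). ARG1 (-1.11), FIT2 (-1.03) and HOM3 (-1.03) lost theirs without gcn5 array A, among others. Of 5536 genes 55 passed, 28 higher and 27 lower, with 3 where dye-swap arrays were averaged, 137 with the slide as a random block and 105 with a dye term per slide run. The count was 12 without gcn5 array A, 36 without gcn5 array B, and 16 and 34 without gcn5 ts2 arrays A and B.

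In esa1 the interaction was lower for glycolysis genes, all of which rose in esa1 and most of which rose in ts2. Of 16, 12 were lower and none higher, and 16 were lower adjusted over the list alone (median -0.89, adjusted p = 1.3e-24, and adjusted p = 0.066 with an estimated correlation). TDH1 had -2.0 ± 0.22 and PGI1 -0.87 ± 0.14. G1/S genes had 9 of 46 lower, 17 adjusted over the list alone (median -0.6, adjusted p = 1.6e-10, and adjusted p = 0.16 with an estimated correlation), among them POL30 (-1.63 ± 0.26), which encodes the replication clamp. The water channel gene AQY2 (-2.24 ± 0.24) and the endonuclease gene HO (-2.23 ± 0.34) were lower, and GRE1 (1.98 ± 0.57), FMP48 (1.79 ± 0.24) and the spore wall gene SPS100 (1.71 ± 0.29) higher. GRE1 lost its call without any of 6 arrays, for example without esa1 array A (1.75). Of 5504 genes 269 passed, 93 higher and 176 lower, with 37 where dye-swap arrays were averaged, 408 with the slide as a random block and 1027 with array weights. Without esa1 array A or B 73 and 134 passed, and without esa1 ts2 array A or B 122 and 104.

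The remaining interactions called few genes. For elp3 they were 40 of 5515, 18 higher and 22 lower. Called whichever array was left out were the carnitine acetyltransferase gene CAT2 (-1.94 ± 0.21), PRM8 (-1.72 ± 0.24) and the replication factor gene RFC5 (-1.65 ± 0.25). The arrays labelled elp3, elp3 ts2 and hpa2 ts2 were of slide run 1, which held no ts2 array. Leaving out 1 array cannot show an effect of that run. RFC5 was also called for hpa2 and hat1, but all interactions subtract the same ts2 arrays, so its calls are not independent. SPS1 (2.15 ± 0.45), CHC1 (2.01 ± 0.46) and SNU66 (1.93 ± 0.39) were higher and lost their calls without elp3 ts2 array B (1.9, 2.06 and 1.79) and at least 1 other array. Without array B of those labelled elp3, SPS1 moved to 1.29 and CHC1 to 1.02. For hpa2 they were 100 of 5470, 34 higher and 66 lower, with RFC5 (-2.34 ± 0.25), NFG1 (-2.76 ± 0.42) and FYV12 (2.18 ± 0.39) called whichever array was left out. Without hpa2 ts2 array B, THI13 (-2.93, and -2.46 without it), ATP20 (2.46, and 2.36) and the cell wall iron gene FIT1 (2.23, and 1.14) lost theirs. THI13 moved to -0.9 and ATP20 to 0.83 without hpa2 array B. The hpa2 count was 251 and 47 without hpa2 ts2 arrays A and B and 62 without hpa2 array A, and 254 with the sign of hpa2 array A turned. For hat1 22 of 5383 passed, 9 higher and 13 lower, among them PMC1 (1.73 ± 0.31), AGP3 (-2.89 ± 0.6) and ARG4 (-1.13 ± 0.19). PMC1 lost its call without hat1 array A (1.34) and ARG4 without hat1 ts2 array A (-0.96). Of the 18 arrays left out in turn, MHT1 (1.45) and RFC5 (-1.1) lost their calls in 15 cases each, SDL1 (1.26) in 10 and AGP3 in 5. Among these were WT arrays, 8 for MHT1 and 7 for RFC5, whose absence left the change as it was. MHT1 moved to 0.69 without hat1 array B. The hat1 count was 51 without hat1 array A, 13 without hat1 ts2 array A, and 6, 5, 47, 10 and 8 without ts2 arrays A to E, and 13, 14, 10, 12 and 7 without WT arrays A, B, C, D and F. Gcn4 genes tested lower for hat1 (median -0.38, 3 of 69 lower, 14 adjusted over the list alone, adjusted p = 4.4e-14, and adjusted p = 0.15 with an estimated correlation). For sas3 none of 5493 genes passed in limma, with 170 at an unadjusted p under 0.05, and 9 and 8 passed without sas3 array A or B and 5 without either sas3 ts2 array. With the slide run as a block 18 genes passed for elp3, 5 for hat1 and 38 for hpa2, and within its own slide run hat1 had 0, with 506 at an unadjusted p under 0.05. On the deposited scale limma called 0 genes in all 6 interactions, and the median gene lay at -0.36 for elp3, -0.19 for esa1, -0.4 for gcn5, 0.17 for hat1, 0.43 for hpa2 and 0 for sas3.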

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

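The random splits of arrays were written before the result was seen, and the tests on chromosome IX, SLH1 and a-specific genes were chosen only after.

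On chromosome IX the esa1 genes had a median of -0.41 (90 lower, 9 higher of 205), while WT array G stood apart from the other WT arrays at -0.19 and WT array C of the same slide run lay at 0.07. The esa1 mutation was excluded as a sufficient account, since a ts2 array of slide run 3 without it lay as low as -0.4. Genes of other chromosomes within 4 spot numbers of a chromosome IX spot lay 0.31 or more above chromosome IX on the 2 esa1 arrays. This argues against a shift shared with those spots there. On the other 4 mutant arrays of run 3 they lay at -0.11 to 0, against -0.4 to -0.13 for that chromosome. No print layout was used, so a printing fault of the chromosome IX spots themselves was not excluded. A WT reference of slide run 3 that differs for this chromosome may account for it, since 6 of 6 mutant arrays of that run lay below all 24 of the other runs. That was left open, as chromosome XVI moved too on the 3 mutant arrays of the run with the test in Cy3 (0.21, 0.23 and 0.29), though not on the 3 in Cy5 (-0.08 to 0.02), and nothing here is called biological.

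SLH1 rose in all 7 ts2 groups, lowest 2.91 on 18 arrays, and lay between -0.26 and 0.34 on the other 20. In gcn5 and esa1 HSP26 rose by 2.02 and 1.84, while SLH1 lay at 0.25 ± 0.2 and 0 ± 0.2. At the ratio of this pair in ts2, SLH1 would have risen by 2.5 and 2.28. This argues against the general stress response as a sufficient account, as far as HSP26 stands for that response. That test replaced a first form, which could not decide, and both were written after the values were seen. An altered TAF1 locus may raise SLH1, which lies close to TAF1 with 2 genes between them, but the lowest value of 2.91 could not tell this from an effect of ts2 on SLH1.

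In gcn5 ts2, 3 of 7 a-specific genes rose. A strain of the other mating type might give this. However, ASG7 (0.02 ± 0.21), STE6 (0.37 ± 0.34) and BAR1 (0.25 ± 0.42) did not pass. Only 1 of 7 genes (ASG7) lay below 1 by over 2 standard errors, which could not tell. A response to pheromone might give it too, but 45.5 percent of the other pheromone response genes rose (10 of 22, with 3 lower), which could not tell either. No explanation was excluded, and no biological one was accepted.

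Other groupings of the arrays were tried for the count in ts2. Of 100 splits of the 14 ts2 and WT arrays, 1 called as many genes as the 3617 of the true one, namely that one itself, and the highest other called 2646, with 4 of 6 ts2 arrays on the same side.

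Arrays far from the others of their group were found in 8 of 90 sets, where chance gives about 1 in 20. They were the COS and PAU median of ts2 array B (-0.95), TFS1 (3.76) and DDR2 (3.85) on ts2 array A, RPS28A on ts2 array E (-2.79), the chromosome IX median of WT array G (-0.19), the G2/M and M/G1 median of WT array H (0.16), and the proteasome (0.3) and TFIID (0.17) medians of WT array A.

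The interaction test called genes in the following cases, but 0 passed in any of them on the deposited scale. With the arrays labelled elp3 40 genes passed, among them SPS1 (2.15), CHC1 (2.01), SNU66 (1.93), CAT2 (-1.94), PRM8 (-1.72) and RFC5 (-1.65). With esa1 269 passed, among them GRE1 (1.98), FMP48 (1.79), SPS100 (1.71), AQY2 (-2.24), HO (-2.23) and TDH1 (-2). With gcn5 55 passed, among them AGA2 (3.76), MFA2 (3.52), MF(ALPHA)2 (2.8), ARG1 (-1.38), FIT2 (-1.27) and HOM3 (-1.17). With hat1 22 passed, among them PMC1 (1.73), MHT1 (1.45), SDL1 (1.26), AGP3 (-2.89), ARG4 (-1.13) and RFC5 (-1.1). With those labelled hpa2 100 passed, among them ATP20 (2.46), FIT1 (2.23), FYV12 (2.18), THI13 (-2.93), NFG1 (-2.76) and RFC5 (-2.34). Several rest on 1 array, since with 1 array left out THI13 moved to -0.9, ATP20 to 0.83, FIT1 to 1.14, CHC1 to 1.02, SPS1 to 1.29 and, for hat1, MHT1 to 0.69. For hat1 MHT1 and RFC5 lost their calls in 15 of 18 such cases and SDL1 in 10.

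Among spots without a gene name, 427 of 1282 passed in ts2 (270 higher, 157 lower), and 0 passed on the WT arrays against 0 in limma.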

How the results depend on the processing

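Counts of genes past the threshold and calls of named genes both changed with the processing, and the cause was not tested for any of the changes below. Spot signal over background was not analysed here. Of 820 named values (570 called) 275 calls were lost on the deposited scale, 84 with the slide run as a block, 67 with averaged dye swaps, 58 without WT arrays in the fit, 27 with array weights, 26 with no dye term, 9 with a dye term per slide run, 5 with no dye sign for WT and 3 with the slide as a random block. Own-run fits lost 53 of 480 calls, leaving out ts2 of run 3 15 of 120, and turning hpa2 A 12 of 20. Leaving out each array in turn lost 121 calls at least once. No missing-value filter, no dye sign for WT and genes above 0 on all arrays moved none of the 19 counts by over 1.5 times. Alternatives not planned (WT sign, WT left out, weights, complete genes, run block, chromosome IX left out, ts2 of run 3 left out, hpa2 A turned) were chosen after seeing the data. Own-run fits were not run for hpa2 and its interaction (the mutant lies in several slide runs) or for the elp3 interaction (no ts2 array in the run).

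Groups are named by their labels. Values as deposited gave 2138 genes in ts2, 3 in elp3, 4 in esa1, 29 in gcn5, 7 in hat1, 2 in hpa2, 2 in sas3, 178 in elp3 ts2, 1415 in gcn5 ts2, 118 in hat1 ts2, 334 in hpa2 ts2 and 470 in sas3 ts2, and 0 in the elp3, esa1, gcn5, hat1 and hpa2 interactions. On that scale TAF1 turned to -0.09 in ts2 and -0.5 in esa1 ts2, and in esa1 ts2 ESA1 to -0.26, HTB1 to 0 and PUP1 to -0.26. A separate dye term per slide run gave 141 in elp3, 4 in hpa2 and 20 in sas3, and 89, 105 and 36 in the elp3, gcn5 and hat1 interactions. Averaged dye swaps gave 1055 in esa1, 547 in gcn5, 277 in hpa2 and 14 in sas3, and 13, 37, 3, 11 and 3 in the elp3, esa1, gcn5, hat1 and sas3 interactions. The slide as a random block (correlation 0.23) gave 408, 137 and 79 in the esa1, gcn5 and hat1 interactions. Own-run fits gave 0 in elp3, 1779 in gcn5, 2 in hat1, 1 in sas3 and 0 in the hat1 interaction. HPA2 turned to 0.29 in ts2 with slide run 2 only.

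With WT left out of the fit 13 passed in elp3, 9 in hat1 and 1 in hpa2, and 19, 27, 5 and 49 in the elp3, gcn5, hat1 and hpa2 interactions. Array weights gave 16 in elp3, 3038 in esa1, 3 in hpa2 and 68 in sas3, and 15, 1027 and 7 in the elp3, esa1 and hpa2 interactions. The slide run as a block gave 5 in elp3, 861 in esa1, 474 in gcn5, 2 in hat1, 1 in hpa2 and 2 in sas3, and 18, 5 and 38 in the elp3, hat1 and hpa2 interactions. Without ts2 of slide run 3, 3 passed in the hat1 interaction. With hpa2 array A turned 7 passed in hpa2 and 254 in its interaction, and in hpa2 SPR6 turned to -0.65, COG2 to -0.35, SNX4 to 0.43 and MAL32 to 0.2. The correlation of ts2 with esa1 was 0.46 with ts2 arrays of other runs. With an estimated correlation 0 list tests passed.

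The letters A and B are a dye orientation shared by all groups of 2, and the main fit blocks on it through the dye term. Deviations of A arrays from their group means correlated at -0.13 to 0.57 (median 0.12, 38 of 66 over 0.1), and whether the dye term removes this was not tested. Without that replicate block (no dye term), ts2 had 3509 genes, hpa2 13, and the elp3, hat1 and hpa2 interactions 23, 4 and 48, and 15 of 19 counts, that of ts2 among them, stayed within 1.5 times.

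Leaving out each array in turn gave 3403 to 3660 in ts2, 16 to 62 in elp3, 602 to 1632 in esa1, 419 to 1080 in gcn5, 28 to 66 in hat1, 19 to 231 in hpa2 and 7 to 21 in sas3. It gave 1467 to 2237 in elp3 ts2, 2280 to 3175 in esa1 ts2, 2156 to 3060 in gcn5 ts2, 697 to 1774 in hat1 ts2, 1790 to 2565 in hpa2 ts2 and 1719 to 2732 in sas3 ts2. Interactions ran from 28 to 60 (elp3), 73 to 323 (esa1), 12 to 67 (gcn5), 5 to 51 (hat1), 47 to 251 (hpa2) and 0 to 9 (sas3). LAM1 in hat1 against WT lay at -5.51 without array A and turned to 0.01 without array B.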

Other observations

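Genes close to chromosome ends were lower in ts2. Of 284 genes among the outermost 10 at each of 32 ends, 143 fell and 49 rose (median -0.31, adjusted p = 0.0011 by camera, and adjusted p = 0.086 with an estimated correlation). Without the COS and PAU families 125 of 255 fell and 49 rose (adjusted p = 0.0042, and adjusted p = 0.088 with an estimated correlation). In esa1 ts2 149 of 282 fell and 40 rose (median -0.56, adjusted p = 2.5e-06, and adjusted p = 0.084 with an estimated correlation), and in sas3 ts2 133 of 282 fell and 29 rose (median -0.49, adjusted p = 3.2e-06, and adjusted p = 0.084 with an estimated correlation). The set was called in the other 4 double mutants too, with medians from -0.38 to -0.29. None of these calls passed in camera with an estimated correlation (adjusted p = 0.084 to 0.086). In esa1 alone 54 of 283 fell and 29 rose (median -0.23, adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation). The set was also called in sas3 alone, though only 2 of 280 fell (median -0.1, adjusted p = 4.7e-05, and adjusted p = 0.084 with an estimated correlation). In the sas3 interaction the set was called by camera with 0 of 280 genes passing and a median of -0.01. There the adjusted p was 0.026, and 0.35 with an estimated correlation, so a preset-correlation call can arise with hardly any shift. It was not called in elp3, gcn5, hat1 or hpa2 alone (adjusted p = 0.17, 0.14, 0.18 and 0.22). In hat1 ts2 92 of 278 fell and 20 rose, with a median of -0.29 that rose to -0.01 on the deposited scale. This set was chosen after seeing the data.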
